A study of Mus musculus with 10 samples.

How the data were processed

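Renin cells were obtained from the kidney cortex of adult Ren1c-YFP reporter mice after aortic coarctation or a sham operation, and RNA was measured in each kidney separately by RNA-seq. Per the labels' protocols, cells that were alive (DAPI negative) and carried yellow fluorescent protein were collected with a cell sorter, 1000 from each kidney, and their cDNA was made with SMART-Seq v4. The labels' design text names the mice as biological replicates. The series holds 10 libraries, with the left and the right kidney of 3 mice with coarctation and of 2 sham mice. Groups were taken from the sample labels, and the kidneys of each mouse were matched by the mouse number in those labels.

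The deposited table holds 3 values for each of 32648 genes in each library, listed by gene symbol. The abundance columns are TPM per the file headers. The count columns are estimated counts per the file headers, not whole numbers, and a column of the deposited file states that these estimated counts were computed from TPM scaled by transcript length and library size. The length columns give the average transcript length in bases per the file headers. Per the submitters' processing notes, FastQC and the mouse build GRCm38 (mm10) were used, with no versions. The aligner, the quantifier and the transcript annotation are not given in the sources used here. Gene positions were taken from GENCODE vM21 on GRCm38 by symbol, and 76 of the 77 genes looked up had a position. The exception was the EYFP transgene. Exon numbers are those of the transcript with the most exons.

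The estimated counts were rounded and analysed in R 4.3.3. Genes with too few counts were removed with the filterByExpr function of edgeR 4.0.16, which left 18825 genes, and library sizes were scaled by TMM. The 5 comparisons were coarctation right minus left, sham right minus left, the difference between these changes, coarctation minus sham in left kidneys, and coarctation minus sham in right kidneys. Each was a contrast in a single edgeR quasi-likelihood model of the 4 groups over all 10 libraries, with a common dispersion of 0.45 and 6 residual degrees of freedom. This model treats the 10 kidneys of the 5 mice as independent, so the comparisons of right with left kidneys are unpaired in it. p-values were adjusted over all tested genes by the Benjamini-Hochberg method, and 0.05 was the threshold. Standard errors of log2 changes come from the same model. TPM values are given as mean ± SD over the mice of a group (n = 3 for coarctation, n = 2 for sham).

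Gene groups were 27 fixed lists of renin cell functions, signalling and stress pathways, markers of other kidney and blood cells, and mitochondrially encoded transcripts. Counts of the last are uncertain, since Gm29216, treated here as a nuclear copy of mitochondrial sequence, held 19294 to 47157 TPM per library. How reads were divided between such copies and the mitochondrial genes is not known. Lists with at least 3 tested genes were compared with all other genes by camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, and p was adjusted over the 27 lists. The correlation between genes was also estimated from the residuals, and fry, a self-contained rotation test, was run as a second alternative. Because camera compares a list with the other genes, its direction can differ from the sign of the list's median. These choices, the lists and the rule for naming genes were fixed before the data were examined.

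The rule named Ren1, Akr1b7, Lmna, Acta2 and Myh11 in every comparison. It further named up to 10 higher and 10 lower genes past the threshold, or, where none passed, the 5 genes with the smallest p among those with a mean log2 CPM of at least 2 and a change in the same direction in every mouse (or no overlap between groups), without predicted genes. It also named the 4 members with the smallest p of each list described. A gene that the rule selects is not reported here, although counts over lists and alternatives include it. Any other gene named in the text was chosen after its values were seen.

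Depth was 20029817 to 32006229 estimated counts per library. The reads carry no molecular identifiers, so that errors computed from counts within a library would cover counting error only, and variation between mice was estimated from the replicates. On data simulated from these libraries with 200 changed genes, the test of coarctation right against left recovered 46% of genes changed 4-fold and 80% of those changed 8-fold, and called 4 of 18600 unchanged genes. In the same comparison 11 unchanged genes were called with mouse as a block, 85 by DESeq2 and 4 by limma-voom. For the sham kidneys the shares were 18% and 54%, for the difference between the changes 2% and 32%, for left kidneys 26% and 66%, and for right kidneys 26% and 74%. Changes of 2-fold were recovered in 0% to 4% of genes by the main test, and for coarctation right against left in 16% with mouse as a block and 10% by DESeq2. None of 20 lists drawn at random was called by the main test in any of the 5 comparisons, and a list shifted on purpose was recovered in each. Simulated genes were drawn independently of each other, so these lists carried no correlation between members. In the real data it was estimated at 0.198 for the unfolded protein response list and 0.851 for mitochondrially encoded transcripts. The simulation therefore cannot tell how often correlated lists are called wrongly. With mouse as a block, 2 of 20 random lists were called between sham kidneys.

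The pairing of kidneys was checked by correlating, over genes, each library's deviation from its group mean. Kidneys of the same mouse had correlations of 0.127, 0.0496 and 0.0307 in the coarctation mice and 0.398 in the sham mice, which is a single value, since the deviations of 2 mice from their mean mirror each other. Of the 6 coarctation libraries, 4 correlated best with the other kidney of their mouse, and those of mouse 3 did not. Since the pairs are kidneys of the same animal, a model with mouse as a block (3 residual degrees of freedom) was fitted as an alternative for the within-mouse comparisons.

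The other alternatives were the Wald test of DESeq2 1.42.0, limma-voom with mouse as a random effect (within-mouse correlation 0.317), RLE and upper quartile scaling, no low-count filter, a stricter filter, only the groups compared, and each library and each mouse left out in turn. A block by mouse number was fitted between coarctation and sham mice. The share of counts in proximal tubule markers and, chosen after the results were seen, in collecting duct markers were used as covariates. Where a left-out library leaves 1 kidney in a group, that kidney is assumed to vary like the other groups. An alternative pseudocount was not applicable, since counts were available. No library was left out of the main results. Genes were not divided into isoforms, because the table holds gene sums only. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.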

Results

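RNA was measured in renin cells sorted from each kidney of mice 8 to 12 weeks old, 72 h after surgery. In the coarctation mice the aorta was narrowed at a point between where the renal arteries leave it. In the sham mice it was neither exposed nor narrowed. In mice the right renal artery usually leaves the aorta above the left, so that such a constriction places the left kidney downstream, although the labels give no pressures. The 10 libraries form 4 groups, the left and right kidneys of 3 coarctation mice and of 2 sham mice. Depth in mice 1, 2 and 3 with coarctation was 23972981, 28127804 and 27611517 estimated counts in left kidneys and 27168627, 32006229 and 25051905 in right kidneys. In sham mice 1 and 2 it was 21774861 and 29357415 in left kidneys and 20029817 and 30055470 in right kidneys. Log2 CPM of the 18825 tested genes correlated between libraries at 0.875 to 0.931. The libraries of sham mouse 1 stood apart on the first principal component (107.3 for the left and 127.7 for the right kidney, 22.7% of variance), where every other library was at 1.12 or lower. Those of coarctation mouse 1 stood apart on the second (72.5 and 110.5, 15.0% of variance), where every other library was at 10.7 or lower. On the third its left and right kidneys lay at opposite ends (-86.6 and 96.8).

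The first comparison, right against left kidney within coarctation mice, asks which genes of renin cells differ between kidneys on the sides of the constriction. Sorted cells from the right kidney held less renin message on average than those from the left, without passing the main test. Whether each renin cell held less or a smaller share of the sorted cells were renin cells is left open. Ren1, which encodes the protease that starts the renin-angiotensin cascade, averaged 38261 ± 9741 TPM in left and 9423 ± 3487 TPM in right kidneys (log2 change -2.20, SE 0.36, 4.59-fold lower, n = 3). It was lower in 3 of 3 mice. Chaperones of the endoplasmic reticulum followed the same direction. Manf, a factor induced by stress in this compartment, averaged 317 ± 23.7 TPM in left and 95.9 ± 15.8 TPM in right kidneys (log2 change -1.90, SE 0.26, 3.72-fold lower), also in 3 of 3 mice.

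None of the 18825 genes passed the edgeR test (0 genes; smallest adjusted p = 0.125), with 871 genes at an unadjusted p under 0.05 (447 higher and 424 lower in the right kidney). DESeq2 called 76 genes and limma-voom called 6, which were Ren1, Manf, Hspa5, Sdf2l1, Aldh7a1 and Vtn. On simulated data for this comparison DESeq2 called 85 of 18600 unchanged genes, and limma-voom called 4. The simulated data also held changed genes. Numbers of unchanged genes called there therefore do not give how many real calls were false, with or without the block. With mouse as a block, edgeR called 5 genes, 4 lower (Ren1, Manf, Kiss1 and Aldh7a1) and 1 higher (Spink8) in the right kidney, of 1117 at an unadjusted p under 0.05, and on simulated data it called 11 of 18600 unchanged genes. Ren1 fell in that blocked test (log2 change -2.23, SE 0.14, adjusted p = 0.00275, against 0.165 without the block). Over all alternatives its adjusted p ran from 1.9e-13 to 1. The change of Ren1 within mice 1, 2 and 3 was -2.52, -2.17 and -2.00 on the log2 scale.

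Ren1 lies on chromosome 1 (GRCm38, 133350510 to 133360325, plus strand, 9 exons). EYFP, the reporter transgene driven by renin regulatory sequence and the basis of the sort, averaged 580 ± 329 TPM in left and 133 ± 63.0 TPM in right kidneys (log2 change -2.28, SE 0.67, lower in 3 of 3 mice). It did not pass (adjusted p = 0.921, and 0.0734 with the block). Akr1b7, an aldo-keto reductase abundant in renin cells (chromosome 6, 34412334 to 34423142), averaged 4978 ± 1535 and 2720 ± 1277 TPM (log2 change -1.06, SE 0.55, lower in 3 of 3 mice), and did not pass either (adjusted p = 1, and 0.0734 with the block). Lmna, which encodes lamins A and C of the nuclear lamina, had a log2 change of -0.10 (SE 0.37). Of the smooth muscle genes, Acta2 had a log2 change of 0.34 (SE 0.41, 1473 ± 387 and 2135 ± 892 TPM) and Myh11 of -0.05 (SE 0.27).

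**Figure D1:**
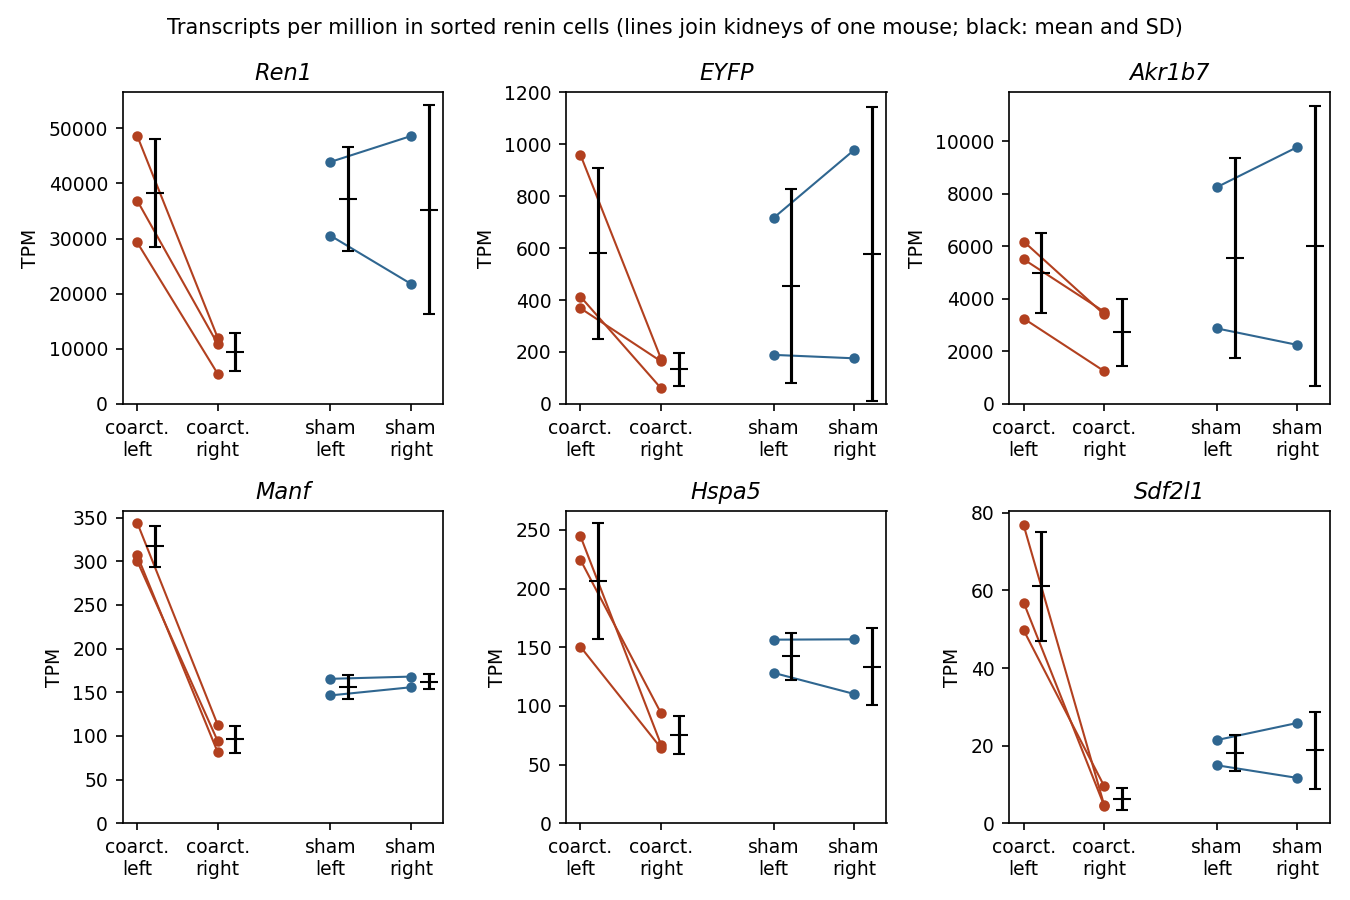
TPM of Ren1, EYFP and Akr1b7 (top) and of Manf, Hspa5 and Sdf2l1 (bottom) in each kidney, with lines joining the kidneys of a mouse, coarctation in red, sham in blue, and black marks for mean ± SD (n = 3 and n = 2). Ren1 averaged 38261 TPM in left and 9423 TPM in right kidneys with coarctation, and 37209 and 35184 TPM in sham mice.

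The list with the smallest p was the unfolded protein response. Of its 24 tested members 23 were lower in the right kidney (median log2 change -0.65), and 16 were lower in all 3 mice. The list fell in the camera test (adjusted p = 7.6e-16), but not when the correlation between its genes was estimated (adjusted p = 0.195 with an estimated correlation) or in fry (adjusted p = 0.113, and 0.0436 with the block). No member passed over all genes, and 5 members were lower when adjusted over the list alone (10 with the block). Sdf2l1, a partner of chaperones in the endoplasmic reticulum, averaged 61.1 ± 14.02 and 6.19 ± 2.89 TPM (log2 change -3.38, SE 0.53, 10.4-fold lower, lower in 3 of 3 mice). Hspa5, the main Hsp70 chaperone of this compartment, averaged 206 ± 49.6 and 74.9 ± 16.4 TPM (log2 change -1.63, SE 0.29, 3.09-fold lower, lower in 3 of 3 mice). Calr, a calcium-binding lectin chaperone, had a log2 change of -1.20 (SE 0.29, 80.1 ± 17.2 and 39.0 ± 2.24 TPM). Hsp90b1, the Hsp90 chaperone of this compartment, named after its values were seen, had one of -0.91 (SE 0.28). On GRCm38, Manf lies on chromosome 9 (106838312 to 106891979, minus strand) and Hspa5 on chromosome 2 (34771970 to 34777547, plus strand). Sdf2l1 lies on chromosome 16 (17130138 to 17132383, minus strand) and Calr on chromosome 8 (84841850 to 84846934, minus strand).

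**Figure D2:**
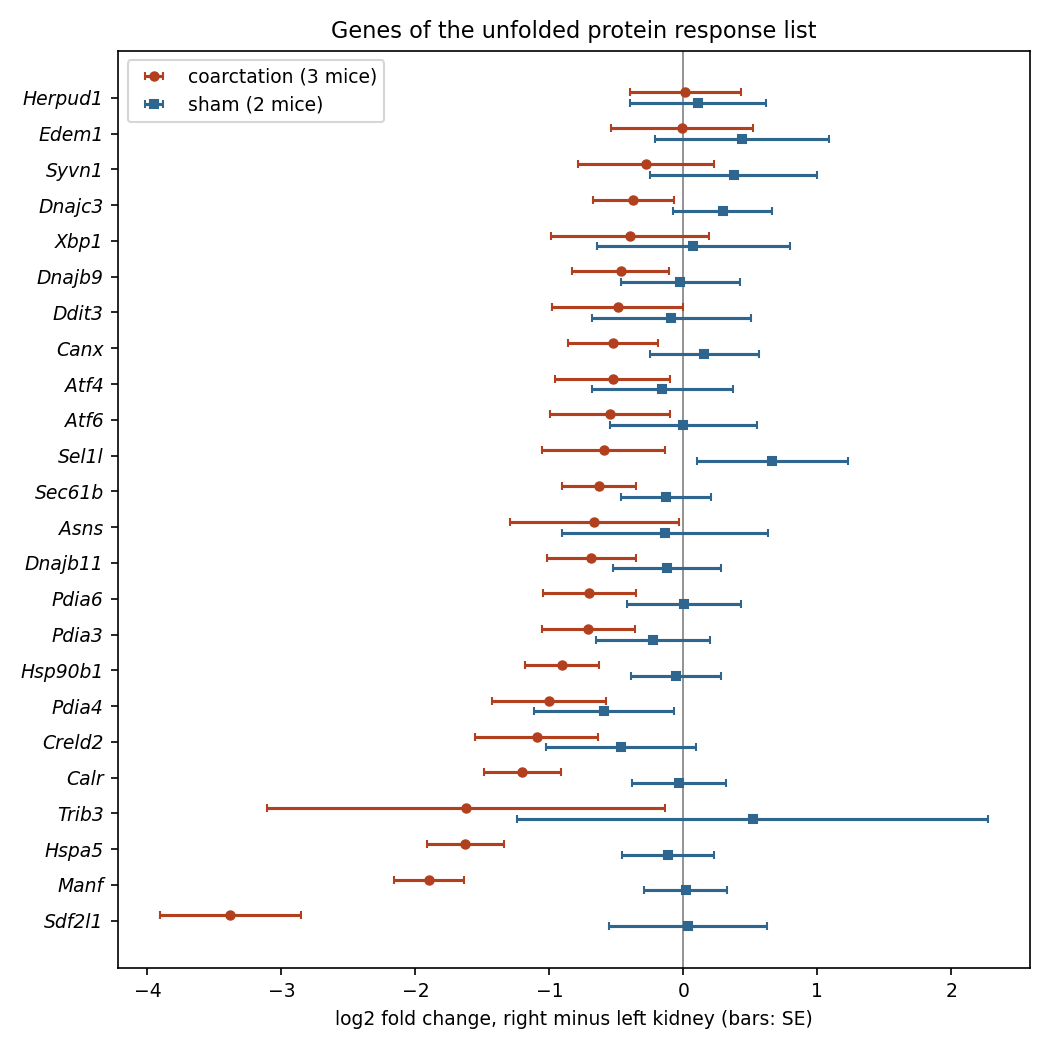
Log2 change from left to right kidney, with SE, for the 24 tested members of the unfolded protein response list in coarctation mice (red circles, n = 3) and sham mice (blue squares, n = 2). The median was -0.65 in coarctation mice and -0.01 in sham mice.

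Genes of sterol synthesis were also lower in the right kidney, in 18 of 21 members (median log2 change -0.45), and the list fell in camera (adjusted p = 0.00239; adjusted p = 0.353 with an estimated correlation). No member passed over all genes or when adjusted over the list alone (0 genes). Fdps, which makes farnesyl diphosphate, had a log2 change of -0.997 (SE 0.45, 58.5 ± 8.31 and 33.3 ± 10.9 TPM). Insig1, a sterol-regulated retention factor, had one of -1.11 (SE 0.68), Stard4, a sterol carrier, of -0.99 (SE 0.52) and the mevalonate kinase gene Mvk of -0.99 (SE 0.70). This call was absent without the left kidney of mouse 3 or without both its kidneys (highest adjusted p 0.279).

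Markers of other kidney cells moved with the same contrast. The loop, distal tubule and collecting duct list was higher in the right kidney, in 16 of 21 members (median log2 change 0.95; camera adjusted p = 0.00356; adjusted p = 0.926 with an estimated correlation). No member passed when adjusted over the list alone (0 genes, and 3 higher with the block). Atp6v1g3, a proton pump subunit of intercalated cells, averaged 32.2 ± 28.2 and 277 ± 327 TPM (log2 change 3.04, SE 0.88, higher in 3 of 3 mice). Atp6v1b1, another subunit of that pump, had a log2 change of 2.66 (SE 0.96), the anion exchanger gene Slc26a4 of 2.66 (SE 1.17) and the water channel gene Aqp3 of 1.52 (SE 0.75). Podocyte markers were lower in 10 of 14 members (median -0.52; camera adjusted p = 0.00518; adjusted p = 0.430 with an estimated correlation), with 1 member lower when adjusted over the list alone. Podxl, which encodes podocalyxin, had a log2 change of -2.97 (SE 1.05; 1.26 ± 0.915 TPM in left and 0.169 ± 0.217 TPM in right kidneys), and Nphs1, which encodes nephrin, of -1.58 (SE 0.93; 0.414 ± 0.271 and 0.158 ± 0.0763 TPM). Both were near the floor. Estimated counts of Clic3, an intracellular chloride channel gene, were 578 and 1 in the left and right kidneys of mouse 1, 1 and 7 in mouse 2, and 419 and 0 in mouse 3.

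Leukocyte markers were called higher in the right kidney (12 of 19 members higher; camera adjusted p = 0.00356; adjusted p = 0.858 with an estimated correlation), although the median log2 change was 0.29 and the mean -0.22. With the block 16 of 19 members were higher (median 1.18, mean 0.92; camera adjusted p = 0.0144; adjusted p = 0.826 with an estimated correlation), and the medians within mice 1, 2 and 3 were 2.90, -1.27 and 0.88. When adjusted over the list alone, 3 members were higher and 2 lower, and with the block 0 genes passed. The major histocompatibility class II genes H2-Aa (log2 change 2.80, SE 0.78) and H2-Ab1 (2.59, SE 0.77) and the class II invariant chain gene Cd74 (2.16, SE 0.62) were higher in the right kidney in 3 of 3 mice. S100a9, a neutrophil gene, had 0 counts in each right kidney and 0, 315 and 16 in the left kidneys of mice 1, 2 and 3 (10.2 ± 16.4 TPM). In fry these marker lists and the sterol list had adjusted p of 0.984 and 0.221.

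Renin cell identity genes were lower in 11 of 20 members (median -0.24) and were not called (camera adjusted p = 0.105), with 1 member, Ren1, lower when adjusted over the list alone (4 lower and 1 higher with the block). With the block the list fell (camera adjusted p = 0.0401; adjusted p = 0.444 with an estimated correlation). Inflammation and chemokines (adjusted p = 0.0401 against 0.0936, and 0.444 with an estimated correlation) and granules and lysosome (0.0405 against 0.105, and 0.826) also fell in it. Gja5, a connexin gene of renin cells, had a log2 change of -1.13 (SE 0.50), and the LIM protein gene Crip1 of -0.44 (SE 0.26). Lists tied to the sensing of force were not called. The median log2 change was -0.05 for the nuclear lamina and LINC complex (adjusted p = 0.917), 0.06 for YAP and SRF targets (0.917), and 0.01 for integrins and focal adhesion (0.917), all from camera. It was -0.06 for mechanosensitive and calcium channels (0.627) and -0.15 for the cAMP and protein kinase A pathway (0.0917). Contractile smooth muscle genes had a median of -0.04 (adjusted p = 0.917) and the renin-angiotensin system of 0.09 (0.960). Proximal tubule markers were lower in 19 of 20 members (median -0.50, adjusted p = 0.627), but with the block in 15 of 20 (median -0.13), and their medians within mice 1, 2 and 3 were -0.82, 0.91 and -0.39. Camera pointed downward for YAP and SRF targets, integrins and the renin-angiotensin system despite their positive medians, and the mean of the contractile list was 0.01.

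Spink8, a Kazal-type protease inhibitor gene, rose in the blocked test (9.22 ± 5.46 and 129 ± 79.0 TPM; log2 change 3.63, SE 0.39, adjusted p = 0.0437, against 0.165 without the block). It moved in the same directions as the intercalated cell genes described below. In sham mice 1 and 2 it was lower in the right kidney (log2 changes -0.74 and -1.62). In left kidneys of sham mice it averaged 67.5 ± 10.4 TPM, above those with coarctation. Whether its signal came from renin cells was not tested. Aldh7a1, an aldehyde dehydrogenase of lysine breakdown, fell in the blocked test (408 ± 232 and 87.0 ± 34.0 TPM; log2 change -2.33, SE 0.25, adjusted p = 0.0437, against 0.272). Kiss1, the kisspeptin gene, fell in it as well (154 ± 105 and 2.66 ± 3.86 TPM; log2 change -6.75, SE 0.70, adjusted p = 0.0437, against 0.244). It overlaps other annotated genes, among them Gm28040 (log2 change 0.20, SE 0.64, in the main test), which makes its counting uncertain. Kiss1 was also lower in the right kidney of sham mice 1 and 2, by less (log2 changes -0.86 and -1.38; 201 ± 80.0 and 91.4 ± 9.73 TPM). Manf fell in the blocked test with an adjusted p of 0.0197. Kiss1, Aldh7a1 and Vtn were named after their values were seen. Vtn, the vitronectin gene, averaged 0.0138 ± 0.0239 TPM in left and 6.83 ± 3.21 TPM in right kidneys. Over all alternatives the adjusted p ran from 6.2e-08 to 0.927 for Manf, 4.6e-11 to 0.669 for Spink8, 4.7e-22 to 1 for Kiss1 and 1.2e-08 to 1 for Aldh7a1.

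With any 1 mouse left out, Ren1 kept its call in the blocked test (adjusted p 0.00064 to 0.0334), whereas Ren1 alone remained of the 5 genes without coarctation mouse 1, sham mouse 1 or sham mouse 2. When the 6 coarctation libraries were divided 3 against 3 in every way, 7 of 10 divisions called at least the 5 lists found here and the highest other number was 10 (lowest adjusted p of the unfolded protein response list in another division 0.000128). In camera that list was also called in other divisions with adjusted p of 0.0452, 0.0029 and 0.00082. The other divisions still mix the sides unevenly, so they are not free of a side difference. The calls of leukocyte, podocyte and tubule markers were absent without the left kidney of mouse 3 (highest adjusted p over alternatives 0.721, 0.124 and 0.763).

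The second comparison asks whether right and left kidneys differ without a constriction. In sham mice the mean renin message of the sides was similar. Ren1 averaged 37209 ± 9457 TPM in left and 35184 ± 18961 TPM in right kidneys (log2 change -0.09, SE 0.42, n = 2), with changes of -0.57 and 0.15 in mice 1 and 2. The chaperones of the endoplasmic reticulum were level as well, with Manf at 156 ± 13.4 and 162 ± 8.63 TPM, Hspa5 at 142 ± 20.0 and 133 ± 32.9 TPM and Sdf2l1 at 18.2 ± 4.61 and 18.8 ± 10.0 TPM. None of the genes passed in edgeR (0 genes; smallest adjusted p = 0.510), with 366 at an unadjusted p under 0.05 (159 higher, 207 lower in the right kidney), while DESeq2 called 28 and limma-voom 0.

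Akr1b7 had a log2 change of 0.11 (SE 0.67), EYFP of 0.35 (SE 0.78), Lmna of -0.02 (SE 0.45), Acta2 of 0.29 (SE 0.50) and Myh11 of 0.19 (SE 0.33). The genes of smallest p, none of which passed (adjusted p = 1), were the kinase gene Ulk4 (log2 change -5.85, SE 1.23, 31.8 ± 36.0 and 0.579 ± 0.484 TPM) and the imprinted gene Zdbf2 (3.62, SE 0.79), then the inducible heat shock gene Hspa1b (-1.71, SE 0.38), R3hcc1l (2.43, SE 0.57) and Nhsl2 (-3.62, SE 0.86), each in the same direction in 2 of 2 mice. Hspa1b has a nearly identical copy, Hspa1a, so that its counts are uncertain. Camera called 0 of 27 lists. The unfolded protein response list had a median log2 change of -0.01 (12 of 24 lower; camera adjusted p = 0.785), and the loop, distal tubule and collecting duct list of -0.90 (16 of 21 lower; 0.460). Mitochondrially encoded transcripts were lower in 13 of 13 members (median -0.38; camera adjusted p = 0.120). With the block that list fell (median -0.34; camera adjusted p = 6.8e-09; adjusted p = 0.876 with an estimated correlation), as did oxidative phosphorylation, lower in 24 of 30 (median -0.14, camera adjusted p = 0.00796, and 0.876 with an estimated correlation). On simulated data the blocked test of the sham kidneys also called 2 of 20 lists drawn at random. With 2 mice, 1 of which stood apart from all others, the main test recovered 18% of simulated 4-fold changes. With mouse as a block the share was 56%, with 10 of 18600 unchanged genes called.

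The third comparison asks whether the change from left to right kidney differed between coarctation and sham mice. Of the lists called between the kidneys of coarctation mice, all but sterol synthesis were also called for this difference, and all 4 calls were lost with an estimated correlation (adjusted p = 0.736 for the unfolded protein response, 0.920 for the collecting duct and leukocyte lists and 0.862 for podocytes). The change of Ren1 was 4.32-fold further downward with coarctation (difference of log2 changes -2.11, SE 0.55, n = 3 and n = 2), without passing (adjusted p = 1, and 0.181 with the block). All 24 members of the unfolded protein response list were lower (median -0.60), and markers of the collecting duct were higher in 19 of 21 members (median 1.42). None of the genes passed in edgeR (0 genes; smallest adjusted p = 0.391), with 575 at an unadjusted p under 0.05 (317 higher, 258 lower), while DESeq2 called 34 and limma-voom 0.

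In camera the unfolded protein response list fell (adjusted p = 2.0e-08; adjusted p = 0.736 with an estimated correlation; fry adjusted p = 0.955), and 3 members were lower when adjusted over the list alone (5 with the block). The difference was -1.91 for Manf (SE 0.40), -3.42 for Sdf2l1 (SE 0.78), -1.51 for Hspa5 (SE 0.45) and -1.17 for Calr (SE 0.45). Of the remaining genes of smallest p, none of which passed, Spink8 had a difference of 4.88 (SE 0.92, adjusted p = 0.719), R3hcc1l of -3.49 (SE 0.72) and Ulk4 of 6.45 (SE 1.42). Ulk4 averaged 13.0 ± 10.7 and 20.5 ± 16.2 TPM in left and right kidneys with coarctation. In sham mice it averaged 31.8 ± 36.0 and 0.579 ± 0.484 TPM, so that the sham right kidneys departed. Akr1b7 had a difference of -1.17 (SE 0.86), EYFP of -2.63 (SE 1.03), Lmna of -0.08 (SE 0.58), Acta2 of 0.05 (SE 0.65) and Myh11 of -0.24 (SE 0.42).

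The loop, distal tubule and collecting duct list rose in camera (adjusted p = 0.00327; adjusted p = 0.920 with an estimated correlation), with 0 members past the threshold when adjusted over the list alone (2 higher with the block). Examples are Aqp3 (3.49, SE 1.20), Atp6v1b1 (3.79, SE 1.48), Atp6v1g3 (3.396, SE 1.33) and the vasopressin-regulated water channel gene Aqp2 (2.98, SE 1.24). Aqp2 averaged 15.9 ± 12.5 and 31.4 ± 25.9 TPM in left and right kidneys with coarctation and 91.0 ± 12.3 and 24.6 ± 21.4 TPM in sham mice. Podocyte markers fell as a list (10 of 14 lower, median -1.14; camera adjusted p = 0.0172; adjusted p = 0.862 with an estimated correlation). Nphs1 (-3.06, SE 1.46) and Podxl (-2.89, SE 1.57) were lower without passing the main test, and averaged at most 2.10 TPM in every group. Leukocyte markers rose as a list in camera (11 of 19 higher, median 0.30 but mean -0.04; adjusted p = 0.00631; adjusted p = 0.920 with an estimated correlation; with the block 15 of 19 higher, median 1.73 and mean 1.34). H2-Aa (3.82, SE 1.20), H2-Ab1 (2.82, SE 1.17) and Cd74 (2.38, SE 0.95) were higher without passing the main test. Without sham mouse 1 the unfolded protein response list alone was called (adjusted p = 2.2e-08), and the tubule, podocyte and leukocyte calls were lost (highest adjusted p over alternatives 0.957, 0.626 and 0.699). With the block, 6 lists were called, among them renin cell identity, which fell (median -0.40; camera adjusted p = 0.0233; adjusted p = 0.643 with an estimated correlation), and mitochondrially encoded transcripts, which rose (median 0.32, 5.7e-05, and 0.776 with an estimated correlation).

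**Figure D3:**
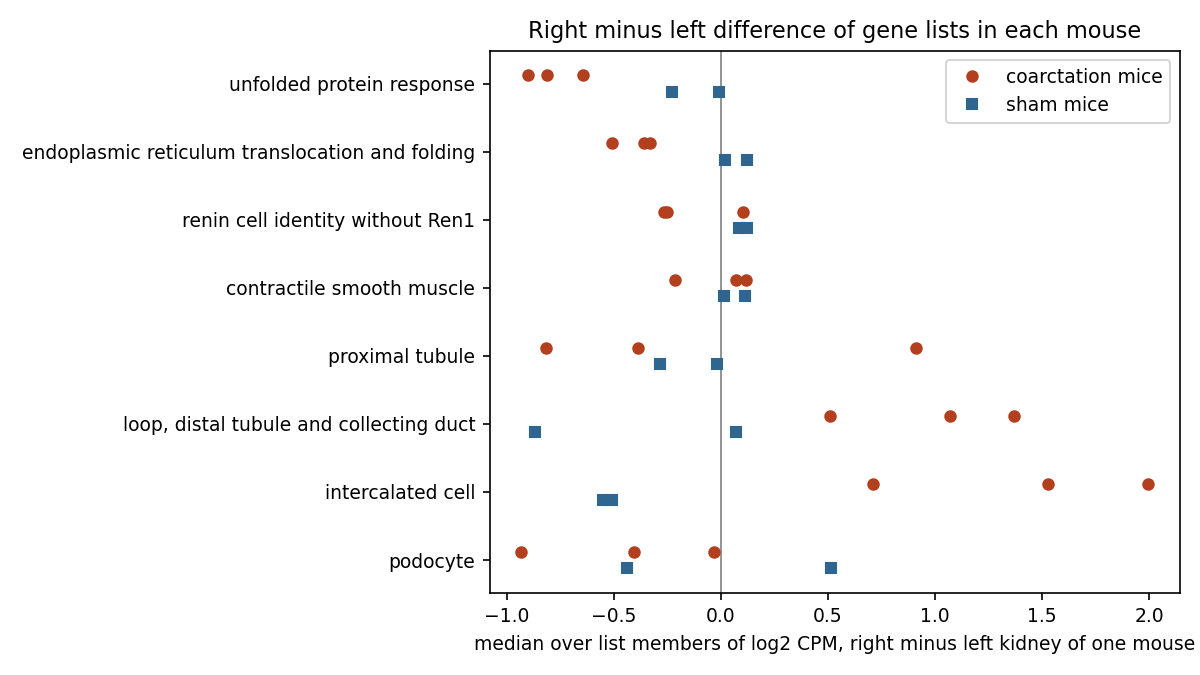
Median over members of the change in log2 CPM from left to right kidney for 8 gene lists, with 1 point per mouse, coarctation in red and sham in blue. For the unfolded protein response the medians were -0.90, -0.64 and -0.81 in coarctation mice 1, 2 and 3 and -0.23 and -0.01 in sham mice 1 and 2.

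The fourth comparison sets the left kidneys of coarctation mice against those of sham mice, and asks what differs on the left side. Renin message was at a similar level. Ren1 averaged 38261 ± 9741 TPM with coarctation and 37209 ± 9457 TPM in sham mice (log2 difference 0.26, SE 0.39, adjusted p = 0.936, n = 3 and n = 2). Genes of the unfolded protein response were higher with coarctation in 22 of 24 members (median 0.63), and contractile smooth muscle genes in 21 of 24 (median 0.41). Manf averaged 317 ± 23.7 TPM with coarctation and 156 ± 13.4 TPM in sham mice (log2 difference 1.29, SE 0.29, 2.45-fold higher, without overlap between groups). None of the genes passed in edgeR (0 genes; smallest adjusted p = 0.912), with 894 at an unadjusted p under 0.05 (346 higher, 548 lower), while DESeq2 called 39 and limma-voom 0.

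In camera the unfolded protein response list rose (adjusted p = 5.5e-08; adjusted p = 0.706 with an estimated correlation; fry adjusted p = 0.718), with 1 member, Manf, higher when adjusted over the list alone. The log2 difference was 1.97 for Sdf2l1 (SE 0.58), 0.88 for the cochaperone gene Dnajc3 (SE 0.35) and 0.79 for Hsp90b1 (SE 0.32). The contractile list rose as well (adjusted p = 5.7e-05; adjusted p = 0.706 with an estimated correlation), with phospholamban (Pln, 1.18, SE 0.38, 184 ± 46.7 and 97.6 ± 27.4 TPM), the actin-binding protein gene Synpo2 (1.14, SE 0.39), Ppp1r14a, an inhibitor of myosin phosphatase (0.83, SE 0.36) and Myh11 (0.53, SE 0.30) as examples. Acta2 had a log2 difference of 0.35 (SE 0.46), Akr1b7 of 0.04 (SE 0.61) and Lmna of -0.15 (SE 0.41).

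Oxidative phosphorylation genes were higher in 27 of 30 members (median 0.25; camera adjusted p = 0.0209), mitochondrially encoded transcripts in 12 of 13 (median 0.44; 0.0271) and proximal tubule markers in 19 of 20 (median 0.68; 0.0379). Each of these lists had an adjusted p of 0.706 with an estimated correlation and 0 members past the threshold when adjusted over the list alone. The respiratory chain genes Uqcrc2 (0.52, SE 0.35), Sdhb (0.41, SE 0.30), Ndufa2 (0.39, SE 0.29) and Cox4i1 (0.38, SE 0.30) are examples. Those of the mitochondrial genome include mt-Atp6 (1.17, SE 0.61), mt-Atp8 (0.81, SE 0.57), mt-Nd4l (0.60, SE 0.46) and mt-Nd6 (0.55, SE 0.42). Among tubule genes were the organic anion transporter gene Slc22a8 (2.06, SE 1.04), the bicarbonate cotransporter gene Slc4a4 (1.32, SE 0.82), the fatty acid transporter gene Slc27a2 (1.23, SE 0.80) and Keg1 (1.20, SE 0.64). The genes of smallest p besides Manf, none of which passed (adjusted p = 0.912), were the ubiquitin ligase gene Cbl (-2.24, SE 0.49, 1.24 ± 0.759 and 6.67 ± 0.664 TPM) and the matrix proteoglycan gene Ogn (3.12, SE 0.73, 56.7 ± 33.9 and 7.88 ± 6.03 TPM), followed by Spink8 (-2.59, SE 0.62) and the calcium pump gene Atp2b4 (-1.37, SE 0.36, 8.93 ± 4.25 and 27.0 ± 5.28 TPM).

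The left library of sham mouse 1 lay at 107.3 on the first component. Without sham mouse 1 or the left kidney of coarctation mouse 3 the contractile call was lost (highest adjusted p 0.933). Without the left kidney of coarctation mouse 3 only the unfolded protein response remained called (1 list). The oxidative phosphorylation, mitochondrial and proximal tubule calls were also lost without the left kidney of coarctation mouse 1 or sham mouse 2 and with upper quartile scaling (highest adjusted p 0.662, 0.993 and 0.877).

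The fifth comparison sets the right kidneys of coarctation mice against those of sham mice, and asks what differs on the right side. Ren1 was lower with coarctation, at 9423 ± 3487 TPM against 35184 ± 18961 TPM in sham mice (log2 difference -1.85, SE 0.38, 3.60-fold lower, n = 3 and n = 2, without overlap between groups), but did not pass (adjusted p = 0.995). Genes of the unfolded protein response were not called as a list (16 of 24 lower, median -0.12; camera adjusted p = 0.207). Mitochondrially encoded transcripts were higher with coarctation in 13 of 13 members (median 0.75) and oxidative phosphorylation genes in 28 of 30 (median 0.35). None of the genes passed in edgeR (0 genes; smallest adjusted p = 0.995), with 720 at an unadjusted p under 0.05 (359 higher, 361 lower), while DESeq2 called 57 and limma-voom 0.

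Akr1b7 had a log2 difference of -1.13 (SE 0.60, 2720 ± 1277 and 6013 ± 5328 TPM), Lmna of -0.23 (SE 0.41), Acta2 of 0.40 (SE 0.46) and Myh11 of 0.29 (SE 0.30). The genes of smallest p besides Ren1, none of which passed, were Hspa1b (1.73, SE 0.36), Kiss1 (-5.03, SE 1.07, 2.66 ± 3.86 and 91.4 ± 9.73 TPM), Ulk4 (5.39, SE 1.18) and Zfp677 (2.92, SE 0.67). For Hspa1b, Ulk4 and Zfp677 the sham right kidneys were the group that departed (51.3, 0.579 and 0.340 TPM). Right kidneys with coarctation (160, 20.5 and 2.35 TPM) were nearer the left kidneys with coarctation (120, 13.0 and 2.36 TPM) and of sham mice (162, 31.8 and 2.47 TPM). Mitochondrially encoded transcripts rose in camera (adjusted p = 4.1e-06; adjusted p = 0.799 with an estimated correlation), with mt-Nd4l (1.25, SE 0.47), mt-Atp6 (1.17, SE 0.61), mt-Atp8 (1.01, SE 0.58) and mt-Co1 (0.75, SE 0.44) as examples. Their counts are uncertain, since the nuclear copy Gm29216 averaged 33271 ± 6886 TPM with coarctation and 28205 ± 12603 TPM in sham mice. Oxidative phosphorylation genes also rose as a list (camera adjusted p = 6.5e-05; adjusted p = 0.841 with an estimated correlation). Examples, none of which passed the main test, are Cox5a (0.62, SE 0.39), Sdhd (0.60, SE 0.38), Uqcrb (0.60, SE 0.38) and Atp5c1 (0.55, SE 0.36).

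Contractile smooth muscle genes rose as a list (19 of 24 higher, median 0.21; camera adjusted p = 0.00239; adjusted p = 0.841 with an estimated correlation). Examples, none of which passed the main test, are the smooth muscle actin gene Actg2 (4.64 ± 2.15 and 0.101 ± 0.143 TPM), Pln (0.90, SE 0.38), Synpo2 (0.71, SE 0.39) and Mustn1 (0.65, SE 0.43). Integrin and focal adhesion genes rose (20 of 30 higher, median 0.14; camera adjusted p = 0.0296; adjusted p = 0.841 with an estimated correlation), with the talin gene Tln2 (1.67, SE 0.51, 13.6 ± 2.88 and 4.59 ± 1.14 TPM), the kinase gene Rock1 (0.67, SE 0.29), Actn1 (0.58, SE 0.35) and, in the other direction, the fibronectin receptor gene Itga5 (-1.46, SE 0.95) as examples.

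Of the markers of other cells, those of proximal tubule (16 of 20 higher, median 0.45; camera adjusted p = 0.00465) and leukocytes (15 of 19 higher, median 1.07; 0.0159) rose, with an adjusted p of 0.841 with an estimated correlation for each. Those of podocytes (9 of 14 lower, median -0.72; camera adjusted p = 0.0139) and endothelial cells (15 of 18 lower, median -1.08; 0.0163) fell, with an adjusted p of 0.717 with an estimated correlation for each. Tubule examples are the glucose transporter gene Slc5a2 (1.25, SE 0.81), Slc22a8 (0.95, SE 0.99), Keg1 (0.63, SE 0.62) and the inositol oxygenase gene Miox (0.56, SE 0.54). Leukocyte examples are H2-Aa (2.08, SE 0.89), the complement gene C1qa (1.74, SE 1.13), H2-Ab1 (1.48, SE 0.85) and Cd74 (1.07, SE 0.68). Podocyte examples, also near the floor, are Podxl (-3.28, SE 1.12; 0.169 ± 0.217 TPM with coarctation and 2.10 ± 2.08 TPM in sham mice), Tdrd5 (-3.29, SE 1.23; 0.0956 ± 0.0742 and 1.09 ± 1.41 TPM) and Nphs1 (-3.10, SE 1.02; 0.158 ± 0.0763 and 1.53 ± 0.296 TPM). Clic3 averaged 0.132 ± 0.186 TPM with coarctation and 34.6 ± 33.1 TPM in sham mice. Endothelial examples are the tight junction gene Cldn5 (-4.66, SE 1.51; 0.0632 ± 0.0208 TPM with coarctation and 1.98 ± 1.56 TPM in sham mice) and Robo4 (-4.03, SE 1.48; 0.0541 ± 0.0323 and 0.953 ± 0.0911 TPM). Others are the phosphatase gene Ptprb (-2.46, SE 0.94; 0.0552 ± 0.0151 and 0.341 ± 0.273 TPM) and the receptor gene Tie1 (-2.22, SE 1.07; 0.279 ± 0.0539 and 1.57 ± 2.03 TPM). These genes were near the floor. The summed share of TPM in the endothelial list was level, at 0.0131 ± 0.00035% with coarctation and 0.0132 ± 0.0020% in sham mice. When adjusted over each list alone, 1 podocyte marker was lower and 0 genes of the other 7 called lists passed. The smallest fry adjusted p was 0.858.

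The right library of sham mouse 1 lay at 127.7 on the first component. Without it the contractile, integrin, endothelial, leukocyte and podocyte calls were lost (highest adjusted p over alternatives 0.561, 0.939, 0.610, 0.422 and 0.263). The mitochondrial and proximal tubule calls were lost without the right kidney of sham mouse 2 (highest adjusted p 0.222 and 0.408) and that of oxidative phosphorylation without the right kidney of coarctation mouse 1 (0.0988).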

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

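Of the tests in this part, those of a lower share of renin cells, of free tubule RNA and of sequencing depth were chosen after the result was seen, and the list for the intercalated cell test was written after Spink8, Hepacam2 and Atp6v1g3 had been seen to be higher.

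The unfolded protein response list stands out because its change from left to right kidney differed between coarctation and sham mice in camera (median difference -0.60 on the log2 scale; adjusted p = 0.736 with an estimated correlation; fry adjusted p = 0.955). A lower share of renin cells in right-kidney sorts could lower it, and this is left open: the median change of the renin cell identity genes other than Ren1 lay above that of the list by 0.648 on average (1.01, 0.376 and 0.563 in mice 1, 2 and 3; SD 0.324), but EYFP (-2.28), Akr1b7 (-1.06) and Gja5 (-1.13) were lower than the list in the right kidney, as dilution would also give. Ren1 takes a large share of counts, which could also shift other genes. Its share was smaller in right kidneys (9423 against 38261 TPM with coarctation), which would raise other genes there, not lower them. With Ren1 counts removed the median change in coarctation mice was -0.53, but for that reason this test adds no support. A biological difference between the sides of the constriction remains possible and was not tested, and against sham mice the list had a median of 0.63 in left kidneys (Ren1 0.26) and of -0.12, not called, in right kidneys (Ren1 -1.85).

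The loop, distal tubule and collecting duct list stands out by the same test (median difference 1.42; adjusted p = 0.920 with an estimated correlation; fry adjusted p = 0.955). A candidate source is a differing amount of intercalated cells or their RNA between the sorts, although the gate on yellow fluorescent protein should remove such cells. A separate list of 20 intercalated cell genes, sharing none with the fixed lists, had a median log2 change of 1.63 in coarctation mice (18 of 20 higher, 11 of 20 in all 3 mice; limma camera p = 1.1e-08 and, with an estimated correlation, p = 0.0447, or 0.0671 adjusted over the 3 added lists; fry p = 0.0763, or 0.114 adjusted) and of -0.55 in sham mice, and against sham mice it was -1.10 in left kidneys (17 of 20 lower) and 0.82 in right kidneys (18 of 20 higher), so that the side that departs is not settled. Its most abundant gene Car2, which other cells also express, averaged 71.6 ± 28.8 TPM in left and 206 ± 174 TPM in right kidneys with coarctation, and Atp6v0d2 1.65 ± 1.08 and 14.2 ± 15.7 TPM. Free RNA from tubules of all segments might be another source, and the gap between intercalated cell and proximal tubule genes, 1.51 on average (2.81, -0.20 and 1.92 in mice 1, 2 and 3; SD 1.55), leaves this open.

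The libraries of sham mouse 1 stand apart on the first principal component and weigh on every comparison with sham mice. Genomic DNA or other background could account for this, since 1007 and 1009 olfactory receptor genes of 1104 had at least 1 count in its left and right kidney libraries, against at most 931 elsewhere. Depth is an unlikely cause, since these libraries were the shallowest (21.8 M and 20.0 M estimated counts, against 32.01 M at most) yet held the most genes with a count (26699 and 27290). Background was not measured directly, and a biological difference of this mouse remains possible. Olfactory receptor genes with a count were also more numerous in the right than the left kidney of coarctation mice 1, 2 and 3. There were 789 against 633, 931 against 881, and 842 against 674. Their summed CPM was higher on the right too (1406 against 825, 1583 against 1367, and 1562 against 1004). Whether background contributed to the changes from left to right kidney in coarctation mice was not tested.

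In the same test of coarctation against sham mice the podocyte list had a median difference of -1.14 (adjusted p = 0.862 with an estimated correlation) and the leukocyte list of 0.30, with a mean of -0.04 (adjusted p = 0.920 with an estimated correlation), or of 1.73 with a mean of 1.34 when mouse was a block (adjusted p = 0.873 with an estimated correlation).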

How the results depend on the processing

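The collecting duct covariate and the alternatives to the blocked test were chosen after the result was seen. Of 3393 values of named genes over the alternatives, 3233 kept their direction and their side of the threshold, 87 passed it (30 higher, 57 lower), 0 lost it (none could, since no gene passed the main test) and 73 turned in direction, none of them past the threshold. The cause was not tested, except that no filter tests more genes (31370) and left-out libraries leave fewer samples. Small changes are mostly missed, since on simulated data the main test recovered at most 4% of 2-fold changes, and for coarctation right against left the mouse block 16% and DESeq2 10%. What depth limits was not tested. Upper quartile scaling shifted the median of all genes by -0.16 (left kidneys) and -0.18 (right kidneys) between coarctation and sham mice, and no filter by -0.11 (left kidneys).

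Genes called, right against left with coarctation (0 in the main test): DESeq2 76, limma-voom 6, no filter 112, collecting duct covariate 3 (Aldh7a1, Manf, Ren1), mouse block 5, and 0 to 4 with libraries or mice left out (3 without the right kidney of coarctation mouse 3, 4 without that mouse). With the block, leaving out a mouse gave 1 to 5 genes (1 without coarctation mouse 1, sham mouse 1 or sham mouse 2, 4 without coarctation mouse 2, 5 without coarctation mouse 3), a stricter filter 7, RLE scaling 5 and upper quartile scaling 6. In sham mice DESeq2 called 28 and no filter 19. For the difference of these changes DESeq2 called 34, no filter 63, and left-out samples gave 0 to 1 (1 without coarctation mouse 3). In left kidneys DESeq2 called 39 and no filter 67. In right kidneys DESeq2 called 57, no filter 70, a block by mouse number 2 (Kiss1, Ren1), and left-out samples gave 0 to 3 (3 without the right kidney of coarctation mouse 3, 2 without that mouse). Mouse numbers are not shared animals between coarctation and sham, and deviations of libraries with the same number correlated at -0.0643 to 0.0566.

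Lists called, right against left with coarctation (5 in the main test): no filter 9, mouse block 8, estimated correlation 0, fry 0, and 1 to 8 with samples left out (1 without the left kidney of coarctation mouse 3, 2 without that mouse, 3 without coarctation mouse 1, 8 without the right kidney of coarctation mouse 2). In sham mice (0 in the main test): collecting duct covariate 1, mouse block 2, and 0 to 9 left out (9 without the right kidney of sham mouse 2). For the difference (4): estimated correlation 0, fry 0, and 1 to 9 (1 without sham mouse 1, 9 without its right kidney). In left kidneys (5): upper quartile 2, no filter 11, stricter filter 3, proximal tubule covariate 2, estimated correlation 0, fry 0, and 1 to 13 (1 without coarctation mouse 3 or its left kidney, 13 without sham mouse 2). In right kidneys (8): estimated correlation 0, fry 0, and 4 to 10 (4 without the right kidney of coarctation mouse 3). The unfolded protein response kept its call in all 23 alternatives for coarctation mice (highest camera adjusted p 3.4e-10), all 22 for the difference (0.0235) and all 23 for left kidneys (0.00417), apart from the estimated correlation and fry.

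Between coarctation and sham mice, a block by mouse number lost the camera calls of proximal tubule in left kidneys (median 0.15, adjusted p = 0.166) and of integrins (0.0505) and endothelial cells (0.0695) in right kidneys, and called the collecting duct list in right kidneys (median 0.93, adjusted p = 0.000299, and 0.534 with an estimated correlation). The mouse block also changed how many members passed when adjusted over the list alone. Right against left with coarctation, renin cell identity had 1 higher and 4 lower (0 and 1 without it), immediate early genes 1 and 1 (0 and 0), leukocytes 0 and 0 (3 and 2), contractile genes 1 higher (0), and inflammation and granules 1 lower each (0). In sham mice, mitochondrial transcripts had 3 lower (0) and immediate early genes 2 lower (1). For the difference, immediate early genes had 3 higher and 2 lower (1 and 0), the unfolded protein response 5 lower (3), renin cell identity 3 lower (1), endothelial cells 0 lower (1), the collecting duct list 2 higher (0), and mitochondrial transcripts and YAP and SRF targets 1 higher each (0). By mouse number, right kidneys had 11 higher mitochondrial transcripts (0) and 4 lower podocyte markers (1). In left kidneys, the proximal tubule list had 1 higher (0).

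With coarctation, right against left, the collecting duct list was also lost without the right kidney of mouse 1 or the left of mouse 2, with that list's share as covariate and with only the groups compared (15 of 23 alternatives kept it; highest adjusted p 0.763), the leukocyte list without either kidney of mouse 1 (19 of 23; 0.721) and the podocyte list without the left kidney of mouse 1 (19 of 23; 0.124). For right kidneys, the contractile call was also lost without coarctation mouse 2 (0.561), the leukocyte call without coarctation mouse 1 (0.422), and the endothelial, podocyte and proximal tubule calls without coarctation mouse 3 (0.610, 0.263 and 0.408).

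Directions turned for 21 of 137 named values, with the range over left-out samples last. Right against left with coarctation: Lmna 0.038 with the collecting duct covariate, -0.37 to 0.16, and Myh11 -0.16 to 0.31. In sham mice, Ren1 -0.93 to 0.44, Akr1b7 -0.084 in limma-voom, -0.0062 with the proximal tubule and -0.039 with the collecting duct covariate, -0.095 with the mouse block, -1.49 to 1.16, Lmna 0.0052 in DESeq2 and 0.0052 with RLE scaling, -0.85 to 0.50, Acta2 -0.58 to 1.05, Myh11 -0.029 to 0.46, and EYFP -1.55 to 1.71. For the difference, Akr1b7 -2.22 to 0.43, Lmna 0.14 with the collecting duct covariate, -0.61 to 0.74, Acta2 -0.72 to 0.92, and Myh11 -0.51 to 0.10. In left kidneys, Ren1 -0.026 to 0.63, Akr1b7 -0.031 with upper quartile scaling and -0.027 with the stricter filter, -0.56 to 1.09, Lmna 0.0089 with the proximal tubule covariate, -0.45 to 0.23, and Acta2 -0.14 to 1.12. In right kidneys, Akr1b7 -1.87 to 0.48, Lmna 0.028 with the collecting duct covariate, -0.75 to 0.60, Acta2 -0.13 to 1.27, Tie1 -3.15 to 1.14, and Tdrd5 -4.22 to 0.0083. Of the 116 values that kept their direction with samples left out, 92 ranged over more than 1.5 times. Among the widest were, in left kidneys, mt-Atp6 0.081 to 2.06, mt-Nd6 0.089 to 1.23, mt-Atp8 0.21 to 1.40, Keg1 0.24 to 1.58 and Slc27a2 0.46 to 2.98, in right kidneys, Slc22a8 0.10 to 3.24, Slc5a2 0.38 to 3.76, Cd74 0.11 to 1.95, Sdhd 0.13 to 1.29 and Uqcrb 0.099 to 0.88, and, right against left with coarctation, Stard4 -1.73 to -0.063.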

Other observations

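Of the tests in this part, none was chosen after its own result was seen, but the list of translocation and folding genes was written after Ssr4, Fkbp11, Fkbp2, Derl3 and Selenok had been seen to be lower, and these were left out of it.

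Genes outside the fixed unfolded protein response list that move proteins into the endoplasmic reticulum and fold them were mostly lower in the right than the left kidney of coarctation mice. Whether this is separate from the unfolded protein response was not tested. A separate list of 37 such genes, sharing none with the fixed lists, had a median log2 change of -0.33 (34 of 37 lower, 18 of 37 in all 3 mice; limma camera p = 1.2e-09 and, with an estimated correlation, p = 0.0280, or 0.0671 adjusted over the 3 added lists; fry p = 0.0277, or 0.0832 adjusted). Srpr, a subunit of the receptor of the signal recognition particle, had a log2 change of -1.002 (SE 0.30; 60.2 ± 12.7 and 33.6 ± 2.01 TPM), the signal peptidase gene Sec11c of -0.87 (SE 0.27) and Ostc, of the oligosaccharyltransferase complex, of -0.59 (SE 0.26), and none of them passed. In sham mice the median was 0.01 (16 of 37 lower), and against sham mice the list was higher with coarctation in left kidneys (median 0.31, 32 of 37 higher; adjusted p = 0.138 with an estimated correlation; fry adjusted p = 0.137) but not lower by camera in right kidneys (median -0.04, 21 of 37 lower). A fall below sham mice was thus not shown.

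Kiss1 lies 20.6 kb from Ren1 on chromosome 1, and a fall shared by the whole region could lower both. The 8 other tested genes within 250 kb of Ren1 had a median log2 change of -0.14 (5 lower and 3 higher, -0.41 to 0.68), and Etnk2, 3.25 kb away, had one of 0.15 (SE 0.65). This argues against a fall of the whole region as large as that of Ren1 (-2.20). A smaller fall, or one shared by Ren1 and Kiss1 alone, is left open.

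A list of 14 principal cell genes, 7 of them in the fixed lists, had a median log2 change of 0.95 from left to right kidney in coarctation mice and of -1.30 in sham mice. Its medians within coarctation mice 1, 2 and 3 were 1.56, -0.67 and 1.80, and within sham mice 1 and 2 they were -1.08 and -2.67. Against sham mice its median was -1.41 in left kidneys (13 of 14 lower) and 0.65 in right kidneys (11 of 14 higher).

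All 10 divisions of the 6 coarctation libraries into 3 and 3 called as many genes as the true groups (0 genes, highest other 0), as any division must when the true groups call 0. Unadjusted p was under 0.05 for 871 genes in the true groups and for at most 1357 in the others. Of the 4 divisions that part the kidneys of every mouse, 1, the true one, called as many genes with the block (5 genes, highest other 0). Of the 10 divisions 7 called as many lists (5 lists, highest other 10). So few divisions cannot give a share under 0.05 with which to judge these counts.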
